A study of Mus musculus with 2 samples.

How the data were processed

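The series holds 2 libraries of sorted CD45+ cells from subcutaneous KP2 tumours, 1 from vehicle-treated and 1 from GB1275-treated mice, each made from a pool of 3 mice. The deposited matrices hold counts, that is whole-number UMIs per gene and cell barcode, with no normalization by the authors found in the values. They list 32285 genes, and every barcode in them holds at least 500 UMIs, as the values show. Per the labels, the reads were processed with Cell Ranger 2.1.1 on mm10; per the file headers, the matrices were written by Cell Ranger 4.0.0. Which of these versions made the counts, and which gene annotation was used, the files do not settle. Gene positions were taken from the GENCODE annotation of GRCm38 by gene identifier. Symbols shared by several identifiers were kept apart by adding the identifier, unless 1 of them held all UMIs.

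Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. In the vehicle library 5509 of 6034 barcodes passed, and in the GB1275 library 4958 of 5319; of the 525 and 361 that failed, 519 and 354 exceeded the mitochondrial limit. Doublets were scored per library with scrublet at an expected rate of 0.05. Its automatic threshold marked 0.127% and 0% of cells, under the limit of 0.5% set in advance, so the cells with the highest scores were removed instead, at 0.8% per 1000 barcodes (243 and 197 cells). This left 5266 vehicle and 4761 GB1275 cells with 74080986 and 58508345 UMIs.

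Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen with library as batch, after leaving out every gene of the gene lists below, mitochondrial, ribosomal and histone genes, and variable segments of antigen receptors. Both libraries were clustered together, without integration, on 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 26 clusters. Marker lists of 22 cell classes were scored in each cluster as the mean centred log2 CPM, with 10 CPM added. A cluster took the name of its highest class when at least 3 of its markers reached 50 CPM and it led the next lineage by 0.5. A cluster below 33.3% of its libraries' median UMIs with no own marker among its 10 leading genes stayed unnamed. Cluster 5, led by hemoglobin genes and by acinar genes of a few vehicle cells, was left unnamed by a choice made after the data were seen. Names carry "like" because they rest on transcripts alone. Clusters 3, 6 and 10 are given by number, because markers of another class were more frequent than their own among their leading genes; by score, 3 and 6 count among the macrophage clusters.

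Each cluster's share of a library has an exact Clopper-Pearson interval, and the ratio of shares an exact conditional interval from the cell counts. For expression, UMIs were summed over the cells of a cluster or class in each library and divided by their total (CPM, the usual scaled unit of counts). CPM values have exact Poisson intervals, and GB1275/vehicle ratios have exact conditional (Clopper-Pearson) intervals. Ratios above 1 or log2 ratios above 0 are higher in GB1275. For the 6 macrophage clusters and for all clusters, CPM was computed in each cluster and averaged with the same weights in both libraries, the clusters' cell numbers in both together, over clusters with at least 20 cells per library; these intervals come from 1000 Poisson redraws. Clusters with at least 50 cells in each library were compared, 19 in all. Intervals have a level of 95% and cover counting error only. With 1 library per group no p-value was computed and no count of changed genes is given.

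Gene lists, 37 in number with 9 of them for other cell types, were fixed before the data were examined. A list's value is the median log2 ratio over members with a mean CPM of at least 10, with 1 CPM added. Its percentile is taken among 10000 random lists of the same size matched on mean CPM in 20 bins, and describes these 2 libraries only; its interval comes from 1000 Poisson redraws. Genes to be named were ranked by a rule, also fixed before the data were examined. It asked for a mean CPM of at least 50, at least 50 UMIs, a ratio of at least 1.5 either way and an interval that leaves out 1. It took the first 12 each way in macrophages and the first 5 each way elsewhere. It left out genes under 10% of their highest CPM in any of the 19 clusters compared (free RNA). Smaller clusters, among them neutrophil-like clusters 16 and 20, did not enter that screen. The rule also added up to 4 members of each list discussed, Itgam, Itgb2 and Tmem173. Among genes that met it, those that lead a cluster were not reported, since clustering selects on them, unless the gene had been left out of the clustering. The genes followed across all clusters were chosen after their values were seen.

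Alternatives changed 1 choice at a time: no barcode filter, a stricter filter (500 genes, 5% mitochondrial), both with doublets removed, doublets kept, Leiden resolutions 0.5 and 2.0, listed genes in the clustering, immune clusters as denominator, the median of all genes set to 0, a mean over cells, the same cluster mix or unweighted sums, cells thinned to 1000 UMIs, other limits on low values, and 10 CPM added. Chosen after the data were seen were 2000 UMIs as a floor, applied to shares and to the CD8 T-like class, the top cell of each library left out of a gene's ratio, the unnamed low-UMI cluster left out of the macrophages without the barcode filter, cluster 7 counted among the clusters with neutrophil markers, counts across clusters with each cluster's median of all genes set to 0, and the cell of each library with the most UMIs of a list of other-cell markers left out of that list.

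The method was tested on simulated counts with known changes drawn from 3 of these comparisons. These were Poisson draws from the pooled profile of both libraries, without variation between cells or mice. They check the calculation and give no error rate for the real counts. Intervals of ratios covered the true value in 95.7% of 6938 genes in cluster 9, 95.6% of 7523 in the CD8 T-like class and 96.3% of 5950 in cluster 2. Of genes made 2-fold different and eligible for the rule, 100% of 41, 100% of 46 and 97.3% of 37 passed it, and of unchanged eligible genes 0%, 0% and 0.517% passed. Simulated counts of macrophage clusters 0 and 1 were also mixed in reversed proportions in the 2 libraries, with no gene changed. Of 2698 genes, 10.3% passed the ratio as unweighted sums and 0% after weighting to the same mix. That shift in mix was larger than the real one, so 10.3% is no error rate for these data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9.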

Results

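Single-cell RNA-seq counts were measured in 2 libraries of sorted CD45+ cells from subcutaneous tumours of KP2, a mouse pancreatic ductal adenocarcinoma line with mutant Kras and deleted p53. The vehicle library and the GB1275 library each pooled 3 mice, and the tumours were taken 14 days after treatment. GB1275 is a small-molecule agonist of CD11b, the integrin chain that myeloid cells carry with CD18. The vehicle library held 6034 barcodes and 81262635 UMIs, and the GB1275 library held 5319 barcodes and 63137043 UMIs. After the filters, 5266 vehicle cells with a median of 10138 UMIs and 4761 GB1275 cells with a median of 8334 UMIs were compared. Each group had 1 library, so there was no replicate check and no test of the treatment was possible. All intervals are 95% intervals of counting error only, and they leave out differences between mice and between library preparations. Intervals of expression count each UMI as independent, so they also leave out differences between cells.

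The first comparison asked which immune cells made up the tumours of each group. The named clusters of neutrophils, the granulocytes that reach tumours from blood, held a lower share of the GB1275 library. These neutrophil-like clusters (2, 16 and 20) held 14.2% of vehicle cells (13.2% to 15.1%, exact Clopper-Pearson) and 10.2% of GB1275 cells (9.36% to 11.1%), a ratio of 0.721 (0.641 to 0.809). CD8 T-like cells, the killer lymphocytes, held 8.26% of vehicle cells (7.53% to 9.04%) and 9.81% of GB1275 cells (8.98% to 10.7%). Their cycling cluster 12, led by the replication gene Rrm2 and the mitotic gene Top2a, held 1.12% (0.854% to 1.44%) and 2.79% (2.34% to 3.30%), a ratio of 2.49 (1.82 to 3.45). Conventional dendritic cell-like cells, which present antigen to T cells, held 1.84% (1.496% to 2.24%) and 2.54% (2.11% to 3.03%).

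The neutrophil-like clusters differed in their ratios. Cluster 2, led by the chemokine receptor gene Cxcr2, had a share ratio of 0.874 (0.769 to 0.992). Cluster 16, led by the alarmin gene S100a9, held 2.26% (1.88% to 2.70%) and 0.861% (0.619% to 1.17%). Cluster 20 expressed Camp, Ngp and Ltf, which encode granule proteins of immature neutrophils. It held 70 vehicle cells and 5 GB1275 cells, so its values come almost wholly from 1 library. Cluster 8, unnamed but with neutrophil markers, held 5.85% and 4.58%. Cluster 7, led by the eosinophil-type receptor gene Ccr3 and with neutrophil and eosinophil markers that scored alike, went the other way, with 4.71% and 6.47%, a ratio of 1.37 (1.16 to 1.63). With clusters 7 and 8 counted, the share ratio of all clusters with neutrophil markers was 0.860 (0.791 to 0.934). The median UMIs of cluster 2 were 2310 and 2339.5, and those of cluster 7 were 681.5 and 687.5, against a floor of 500 UMIs per barcode, and what lay below the floor was not analysed here.

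Macrophage clusters held 44.9% of vehicle cells (43.5% to 46.2%) and 41.5% of GB1275 cells (40.1% to 42.9%), a ratio of 0.924 (0.870 to 0.982). Without the barcode filter, but with doublets removed, that ratio was 1.006 when an unnamed low-UMI cluster led by mitochondrial genes (453 vehicle and 551 GB1275 cells) counted as macrophage, and 0.939 (0.885 to 0.996) without that cluster. Without cells under 2000 UMIs it was 0.993 (0.934 to 1.055), so the lower share was not seen among cells above that limit. Other classes had share ratios whose intervals included 1: 1.08 (0.891 to 1.31) for monocyte-like cells, 1.06 (0.781 to 1.43) for regulatory T-like cells, 0.971 (0.698 to 1.35) for plasmacytoid dendritic cell-like cells, 1.17 (0.795 to 1.71) for B-like cells and 0.992 (0.561 to 1.74) for NK-like cells. The shares describe sorted CD45+ cells with at least 500 UMIs, not the whole tumour. Among immune clusters alone, the named neutrophil-like clusters held 15.2% and 11.4%, and the CD8 T-like clusters held 8.84% and 10.9%. The macrophage clusters held 48.0% and 46.2% of these cells, closer together than among all cells. This denominator left out clusters 5 and 15, although cluster 5 had macrophage as its second class.

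**Figure D1:**
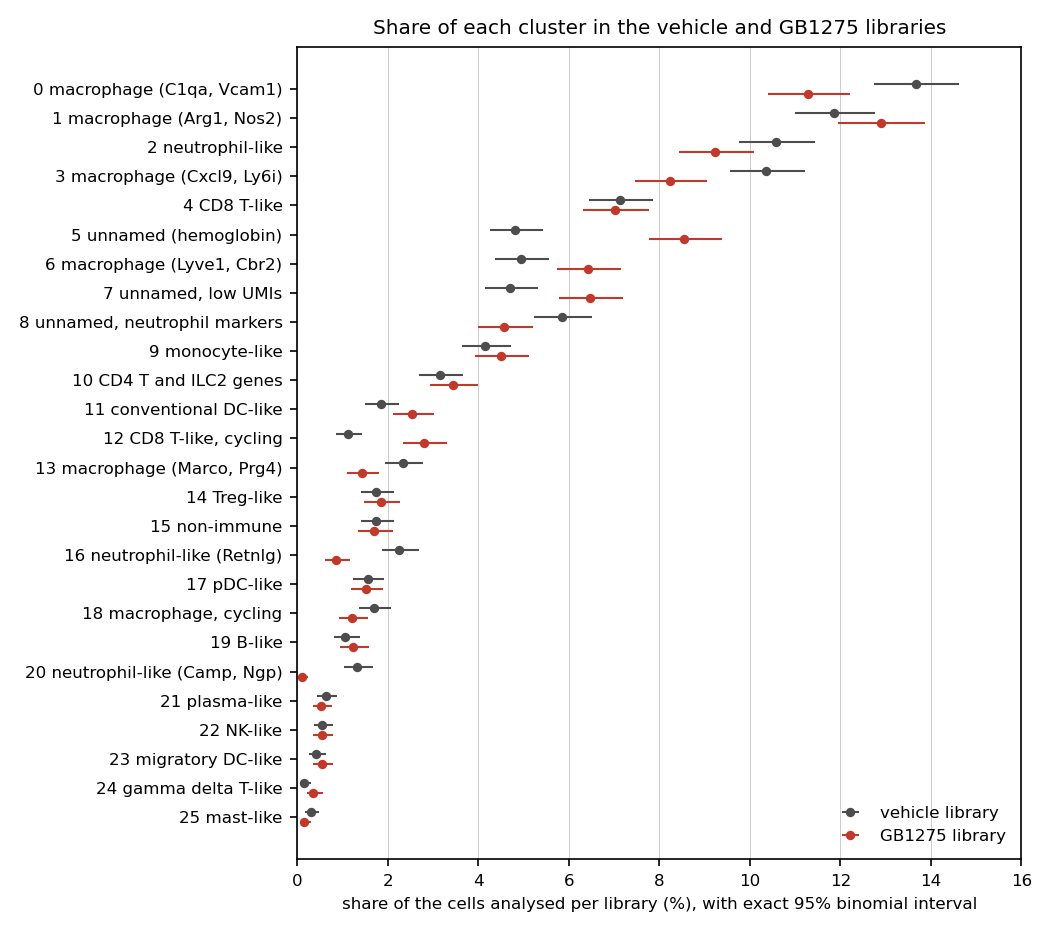
Share of each of the 26 clusters among the cells analysed (x axis, percent) in the vehicle library (grey) and the GB1275 library (red), with points for shares and lines for exact 95% binomial intervals. Cluster 12 (cycling CD8 T-like) lies at 1.12% and 2.79%, and cluster 16 (neutrophil-like) at 2.26% and 0.861%.

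Within the macrophage clusters, the mix differed between the libraries. Cluster 6, which expressed the tissue-macrophage genes Lyve1, Cd163 and Retnla, held 11.003% of vehicle macrophages (9.77% to 12.3%) and 15.5% of GB1275 macrophages (13.9% to 17.2%). Cluster 1, with the arginine-metabolising genes Arg1 and Nos2, held 26.4% (24.7% to 28.3%) and 31.1% (29.1% to 33.2%). Cluster 0, with the complement genes C1qa, C1qb and C1qc, held 30.5% (28.6% to 32.4%) and 27.2% (25.2% to 29.2%). Cluster 3, with the T cell-attracting chemokine gene Cxcl9, held 23.1% and 19.8%. Cluster 13, with the scavenger receptor gene Marco, held 5.21% (4.34% to 6.18%) and 3.44% (2.68% to 4.35%), and cycling cluster 18 held 3.77% and 2.94%. Because the mix differed, expression in macrophages was compared with both libraries weighted to the same cluster mix.

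The second comparison asked whether macrophages and monocyte-like cells differed in interferon, STING and inflammatory genes, the subject that the study's title names. NF-kB targets and inflammatory cytokine genes were higher in the GB1275 library: 20 of 29 measured members in macrophages, with a median log2 ratio of 0.076 (0.052 to 0.093). The neutrophil-attracting chemokine gene Cxcl3 was at 193.8 CPM (UMIs of a gene scaled to a common total) against 367.4 CPM, a ratio of 1.90 (1.84 to 1.95), and the CCR5 ligand genes Ccl3 and Ccl4 had ratios of 1.46 and 1.34. Interferon-stimulated genes were not higher as a group. Of 29 type I interferon response genes, 12 were higher and 17 lower, with a median of -0.055 (-0.074 to -0.010); Ifi27l2a had a ratio of 0.804 (0.779 to 0.834) and Isg15, a ubiquitin-like antiviral protein, 0.873 (0.825 to 0.921), while the DNA-sensor gene Ifi204 had 1.15 (1.09 to 1.21). Of 17 interferon gamma response genes, 8 were higher and 9 lower, with a median of -0.044 (-0.080 to 0.003). Irf8, a transcription factor of the myeloid lineage, had a ratio of 0.814 (0.790 to 0.837), and Gbp2, an interferon-induced GTPase, had 0.851 (0.831 to 0.871).

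STING pathway genes showed no common direction in macrophages: 4 of 8 were higher and 4 lower, with a median of -0.021 (-0.081 to 0.029). Tmem173, which encodes STING (ENSMUSG00000024349, chromosome 18, 35733679 to 35740554), was at 84.9 CPM in vehicle and 76.9 CPM in GB1275 macrophages, a ratio of 0.905 (0.862 to 0.954). The kinase gene Ikbke had a ratio of 0.830 (0.779 to 0.883), and the interferon receptor gene Ifnar1 had 1.09 (1.05 to 1.14). Itgam, which encodes CD11b (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), was at 424 CPM and 460.0 CPM, a ratio of 1.09 (1.06 to 1.11). Itgb2, which encodes its partner CD18 (ENSMUSG00000000290, chromosome 10, 77530252 to 77565708), was at 277.2 CPM and 288.9 CPM, a ratio of 1.04 (1.02 to 1.07). Positions are on GRCm38.

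Most MHC class II genes were higher in macrophages, as were the T cell chemokine genes Ccl5 and Cxcl9, but the medians of both lists lay within the 95% range of random lists. Of 9 MHC class II genes, 7 were higher and 2 lower, with a median of 0.058 (94.0th percentile of random lists); the cathepsin gene Ctss had a ratio of 1.08 (1.07 to 1.09), while Ciita, the class II transactivator, had 0.774 (0.731 to 0.818). MHC class I genes had 9 members higher and 9 lower, with a median of 0.013. The 4 T cell chemokine genes had a median of 0.083, and the intervals of 2 of them included 1: Ccl5 had a ratio of 1.30 (1.28 to 1.33), Cxcl9 1.11 (1.09 to 1.13), Cxcl10 1.01 (0.973 to 1.05), or 0.968 without the top cell of each library, and Cxcl16 1.001 (0.980 to 1.02).

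The percentiles among 10000 random lists of matched expression were 99.98 for NF-kB genes, 1.96 for type I interferon, 12.8 for interferon gamma, 39.3 for STING and 91.5 for T cell chemokines. At Leiden resolution 0.5 the type I interferon median was 0.026 and the T cell chemokine median -0.044, the latter being -0.009 without the barcode filter and 0.027 when the unnamed mitochondrial cluster was left out as well. The interferon gamma median was 0.027 under the stricter barcode filter, 0.015 at Leiden resolution 2.0, 0.010 with listed genes in the clustering and 0.016 as a mean over cells. With cells thinned to 1000 UMIs the STING median was -0.19 and the NF-kB median 0.14.

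Single macrophage clusters went different ways in interferon and chemokine genes. In cluster 1, 20 of 28 type I interferon genes were higher, with a median of 0.13 (0.040 to 0.185). The GTPase gene Iigp1, of the interferon gamma list, had a ratio of 1.48 (1.38 to 1.59) there. In cluster 6, 22 of 32 type I interferon genes were lower, with a median of -0.15 (-0.213 to -0.060), and Ifi27l2a had a ratio of 0.590 (0.549 to 0.634). Iigp1, of the interferon gamma list, had 0.650 (0.585 to 0.722) in cluster 6. Interferon gamma response genes had medians of -0.15 in cluster 0, -0.37 in cluster 6 and -0.40 in cluster 13, against 0.039 in cluster 1. Neutrophil marker genes had medians of -0.42, -1.40 and -1.44 in the same clusters 0, 6 and 13, with 3 of 6 members lower in cluster 0. In cluster 3 all 4 T cell chemokine genes were higher, with a median of 0.34 (0.295 to 0.380), and Ccl5 had a ratio of 1.77 (1.70 to 1.85). In cluster 13, 3 of 4 were lower, with a median of -0.31 (-0.502 to -0.128); Cxcl9 had a ratio of 0.133 (0.0889 to 0.193). All 9 MHC class II genes were lower in cluster 13, with a median of -0.40, and 8 of 9 were higher in cluster 18, with a median of 0.22.

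Monocyte-like cells (cluster 9, 219 vehicle and 214 GB1275 cells) had higher chemokine and cytokine genes and lower interferon gamma response genes in the GB1275 library. All 9 myeloid chemokine genes were higher, with a median of 0.66; Ccl8 had a ratio of 3.43 (2.88 to 4.09), or 1.42 without the top cell of each library, and Ccl7, a ligand of the monocyte receptor CCR2, had 1.93 (1.72 to 2.17). NF-kB genes were higher for 24 of 29 members, with a median of 0.26 (0.235 to 0.328), among them Ccl3 at 2.31 (2.02 to 2.65) and Tnf at 1.79 (1.49 to 2.15). Interferon gamma response genes were lower for 14 of 16 members, with a median of -0.33 (-0.386 to -0.192); Igtp and Gbp4, both GTPases of cell-autonomous defence, had ratios of 0.750 (0.617 to 0.909) and 0.757 (0.610 to 0.936). Type I interferon genes were lower for 22 of 33 members, with a median of -0.089. All 9 MHC class II genes were higher, with a median of 0.21, and the peptide-exchange gene H2-DMb1 had a ratio of 1.33 (1.25 to 1.43).

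The monocyte-like cells also differed in macrophage genes. The mannose receptor gene Mrc1 had a ratio of 2.18 (1.99 to 2.39), and macrophage markers as a list had 8 of 11 members higher, with a median of 0.29. Neutrophil markers had a median of 0.89 there, or 0.26 without the cell of each library that held most of their UMIs. The platelet-factor chemokine gene Pf4 had a ratio of 2.48 (2.26 to 2.73), which was 4.06 under the stricter barcode filter and 1.59 with thinned cells. STING pathway genes had a median of -0.015, MHC class I genes 0.027 and T cell chemokine genes -0.028, the last being -0.35 with doublets kept. The MHC class II median was 0.091 with doublets kept and 0.095 with thinned cells.

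**Figure D2:**
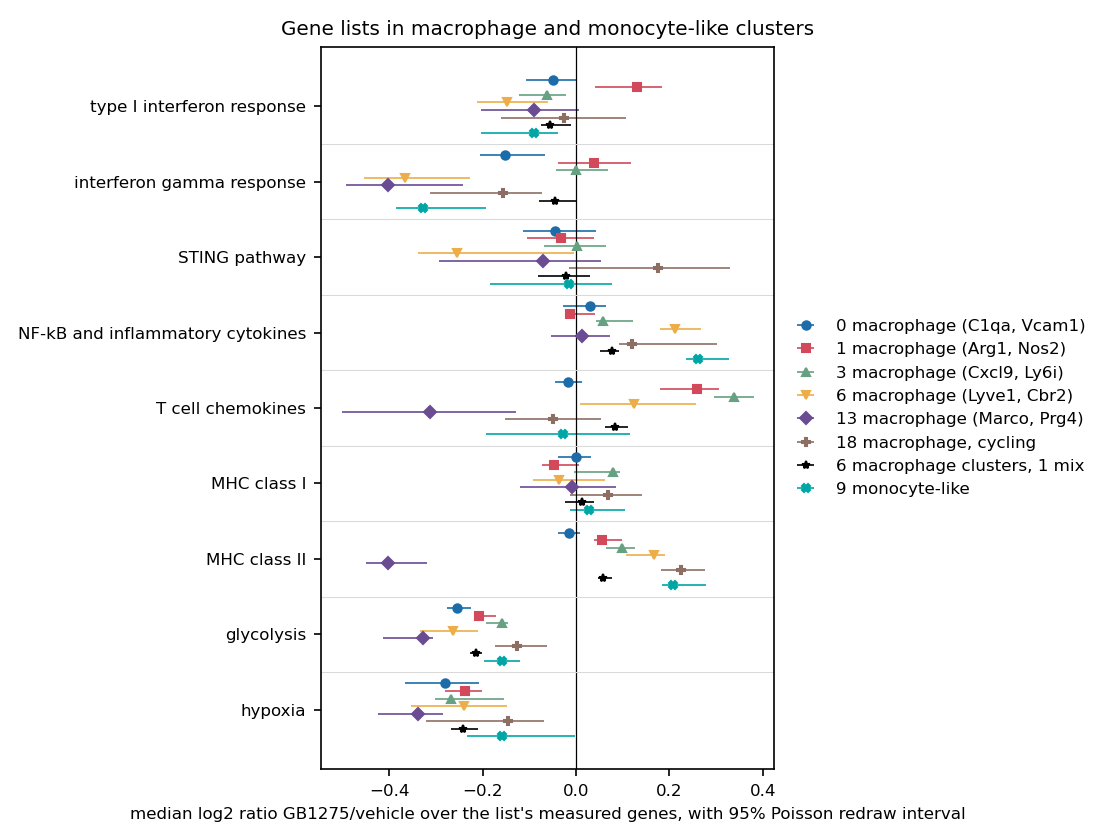
Median log2 ratio of GB1275 over vehicle (x axis) of 9 gene lists in 6 macrophage clusters, in these clusters weighted to the same mix, and in monocyte-like cluster 9, with lines for 95% intervals from Poisson redraws. Glycolysis and hypoxia medians lie below 0 in all of these, while type I interferon genes lie at 0.13 in cluster 1 and -0.15 in cluster 6.

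Glycolysis and hypoxia genes were lower in GB1275 macrophages. All 14 glycolysis genes were lower, with a median log2 ratio of -0.215 (-0.227 to -0.202); the glucose transporter gene Slc2a1 had a ratio of 0.752 (0.726 to 0.779) and the triosephosphate isomerase gene Tpi1 0.808 (0.793 to 0.823). Of 12 hypoxia genes, 11 were lower, with a median of -0.24, and the oxygen-sensing hydroxylase gene Egln3 had a ratio of 0.686 (0.652 to 0.720). The hypoxia median was -0.15 when UMIs were summed over clusters without weighting. All 13 genes of the mitochondrial genome were higher, with a median of 0.12, but this median was 0.011 under the stricter filter and -0.12 without the barcode filter, or 0.095 without both the filter and the unnamed mitochondrial cluster. Dissociation and heat shock genes were lower for 12 of 18 members, with a median of -0.14, or -0.022 with no filter on low values. The heat shock gene Dnajb1 had a ratio of 0.729 (0.701 to 0.759).

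Myeloid chemokine genes had 6 of 9 members higher in macrophages, with a median of 0.17, or 0.34 at Leiden resolution 0.5; Ccl9 and Ccl6 had ratios of 1.30 (1.28 to 1.32) and 1.20 (1.20 to 1.21). Alternative activation genes had 9 of 15 higher, with a median of 0.048 that ranged from 0.001 with genes of at least 50 CPM to 0.18 as unweighted sums. Lipid and lysosome genes had 8 of 13 higher, with a median of 0.077, and the cathepsin gene Ctsl had a ratio of 1.21 (1.19 to 1.24). Cell cycle genes had 16 of 18 lower, with a median of -0.089 that was -0.41 as unweighted sums. Medians of the remaining lists were -0.030 for nuclear oxidative phosphorylation, -0.082 for p53 targets, -0.079 for the unfolded protein response, 0.042 for integrins and adhesion, 0.041 for costimulation, 0.021 for checkpoint ligands and 0.011 for complement. Neutrophil markers, from another cell type, had a median of -0.37 in the same macrophages, and macrophage markers 0.040.

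Single genes that stood apart in macrophages included Tsc22d3, the glucocorticoid-induced leucine zipper (ENSMUSG00000031431, chromosome X, 140539528 to 140600659). It was at 86.5 CPM (83.7 to 89.3) in vehicle and 187.9 CPM (183.7 to 192.6) in GB1275 macrophages, a ratio of 2.17 (2.08 to 2.27). Jaml, a junctional adhesion molecule of leukocytes, had a ratio of 2.13 (2.05 to 2.21), the adaptor gene Sla 1.78 (1.70 to 1.86) and the sphingomyelin synthase gene Sgms1 1.67 (1.58 to 1.76). Retnla, a marker of alternative activation, had a ratio of 1.66 (1.59 to 1.72), or 2.68 when UMIs were summed without weighting. The calcineurin regulator gene Rcan1 had a ratio of 1.65 (1.56 to 1.76), Mertk, a receptor for dying cells, 1.54 (1.48 to 1.61), the histidase gene Hal 1.53 (1.48 to 1.59) and the sialic acid receptor gene Cd33 1.51 (1.46 to 1.57). Lower genes were Eno1b, an enolase copy, at 0.579 (0.541 to 0.618), the heat shock gene Hspa1b at 0.629 (0.621 to 0.637) and the cyclin gene Ccnd2 at 0.655 (0.623 to 0.688).

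Further genes stood apart within single macrophage clusters or in monocyte-like cells. In cluster 0 the oxysterol-making enzyme gene Ch25h had a ratio of 2.79 (2.497 to 3.13) and Cxcl10 had 0.648 (0.605 to 0.693). In cluster 1 the placental growth factor gene Pgf had 0.443 (0.395 to 0.496) and the vasodilator gene Adm 0.567 (0.513 to 0.626). Ccl17, a ligand of CCR4, a chemokine receptor of T cells, had a ratio of 6.30 (5.71 to 6.97) in cluster 3. Without the top cell of each library this ratio was 3.84. Ccl17 was found in 53 vehicle and 33 GB1275 cells of cluster 3, so its higher sum did not come from more cells with the gene. In the GB1275 library 1 cell held 959 of its 2030 UMIs. In cluster 6 the ribonuclease gene Rnase2a had 4.38 (3.52 to 5.49), the lysozyme gene Lyz1 0.286 (0.229 to 0.354) and the gelatinase gene Mmp9 0.385 (0.3503 to 0.424). Without the top cell of each library Lyz1 had 0.388 and Mmp9 0.452. Lyz1 was found in 24 vehicle and 34 GB1275 cells, and 1 vehicle cell held 163 of its 334 vehicle UMIs. Mmp9 is a member of the neutrophil marker list, whose median was -1.40 in cluster 6. Retnla had a ratio of 18.3 (15.8 to 21.3) in cluster 13, or 12.5 without the top cells, and 29.8 in cluster 18, where 1 cell held 296 of its UMIs and the ratio without the top cells was 3.27. In cluster 18, Prtn3, a protease of immature granulocytes, had a ratio of 0.0496 (0.0246 to 0.0896) and the chemokine gene Ccl7 0.314 (0.262 to 0.375). The free RNA screen did not include cluster 20, with genes of immature neutrophils, so it could not leave out free RNA of those cells. In monocyte-like cells the uridine phosphorylase gene Upp1 had 0.449 (0.376 to 0.536) and the eosinophil-type ribonuclease gene Ear2 2.01 (1.74 to 2.31).

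The same few genes recurred across cell types. Fkbp5, an HSP90 co-chaperone that glucocorticoid receptors induce (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), was higher in the GB1275 library in 19 of 19 clusters compared, and its interval lay above 1 in 17. In macrophages it was at 13.8 CPM and 73.2 CPM, a ratio of 5.31 (4.87 to 5.82). Tsc22d3 was higher in 18 of 19 clusters, with 17 intervals above 1. The metallothionein gene Mt2, which is also a leading gene of cluster 1, was higher in 18, with 11 intervals above 1, and the transcription factor gene Klf9 in 15, with 9. Jaml was higher in 14 clusters and Sla in 16. The stress genes Hspa1a and Hspa1b were each lower in 18 of 19 clusters, with non-immune cluster 15 as the exception, the AP-1 gene Jun was lower in 16, and Eno1b was lower in 19. Hspa1a and Hspa1b are near-identical copies, as are Eno1b and Eno1, so how their reads were split between copies is uncertain. Itgam was higher in 14 clusters, Itgb2 in 9 and Tmem173 in 8. These counts include unnamed cluster 5, where the median log2 ratio of all genes was 0.32. With the median of all genes in each cluster set to 0, Itgam was higher in 13 clusters, Itgb2 in 10 and Tmem173 in 9, Klf9 in 16 and Jaml in 15, Hspa1a and Hspa1b were each lower in 17, and the counts of the other genes named here stayed as given.

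**Figure D3:**
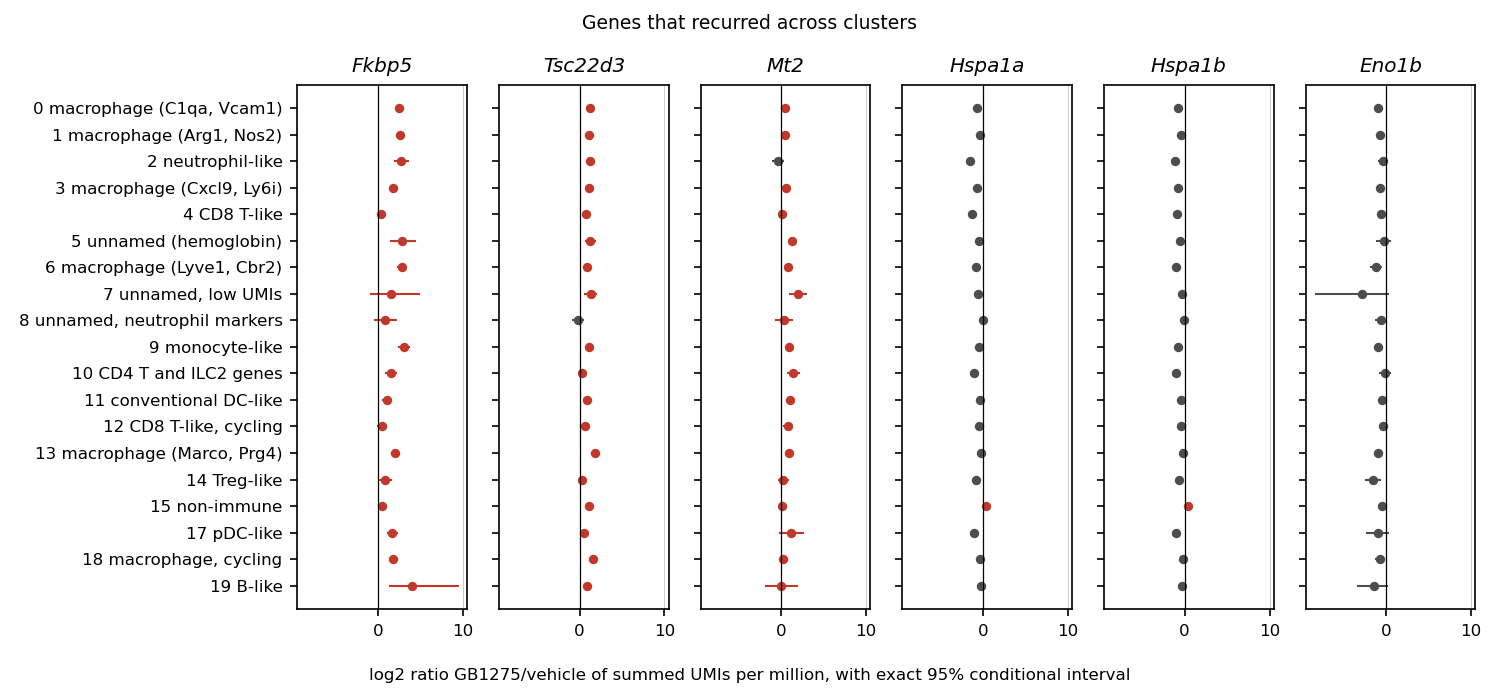
Log2 ratio of GB1275 over vehicle (x axis) of 6 genes in each of the 19 clusters compared, with points for ratios of summed and scaled UMIs (red above 0, grey below) and lines for exact 95% intervals. Fkbp5 lies above 0 in 19 clusters and Tsc22d3 in 18, while Hspa1a and Hspa1b lie below 0 in 18 and Eno1b in 19.

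The third comparison asked whether T cells differed in effector, exhaustion and memory genes. Cell cycle genes were higher in the CD8 T-like class of clusters 4 and 12, with 26 of 29 members higher and a median of 0.17; the mitotic genes Ube2c and Ccnb2 had ratios of 1.77 (1.61 to 1.95) and 1.63 (1.40 to 1.89). Cytotoxicity genes were lower for 8 of 13 members, with a median of -0.14 (-0.163 to -0.066): Ccl4 had a ratio of 0.707 (0.681 to 0.734), while the granzyme gene Gzma had 1.24 (1.18 to 1.30), or 0.956 without the top cell of each library. Exhaustion genes were lower for 7 of 11 members, with a median of -0.14; the ectonucleotidase gene Entpd1 had a ratio of 0.811 (0.730 to 0.900) and Cd160 1.30 (1.18 to 1.43). Naive and memory genes were lower for 5 of 7 members, with a median of -0.26, although Il7r, the interleukin-7 receptor gene, had a ratio of 1.34 (1.17 to 1.53). Tcf7, of the same list, had a ratio of 0.54, or 0.82 without the top cell of each library. Weighted to the same mix of clusters 4 and 12, the medians were -0.096 for cell cycle, 0.004 for cytotoxicity and -0.020 for exhaustion. As a mean over cells the naive and memory median was 0.027 and the cytotoxicity median -0.042.

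Within non-cycling cluster 4, cytotoxicity genes had a median of -0.006 and exhaustion genes 0.008, while NF-kB genes were higher for 22 of 26 members, with a median of 0.17. Neutrophil and macrophage markers had medians of -0.19 and -0.18 in cluster 4. Without the cell of each library that held most of their UMIs these medians were -0.69 and -0.26. Gzma had a ratio of 1.73 (1.64 to 1.82) there, or 1.34 without the top cells. It was found in 60 of 376 vehicle and 43 of 334 GB1275 cells, so its higher sum did not come from more cells with the gene. The heat shock gene Hspa1a had a ratio of 0.398 (0.365 to 0.434) in cluster 4. In cycling cluster 12, cytotoxicity genes were higher for 10 of 13 members, with a median of 0.25, and Ifng, the interferon gamma gene, had a ratio of 1.83 (1.48 to 2.27). Against that direction, Gzma and Ccl4 had ratios of 0.271 (0.232 to 0.316) and 0.377 (0.338 to 0.421) there, or 0.433 and 0.535 without the top cells. Ccl3, of the same list, had a ratio of 0.232 there, or 0.139 without the top cells. Cell cycle genes were lower there for 25 of 29 members, with a median of -0.14. Among markers of other cells, cluster 12 had medians of -7.25 for the 4 measured erythroid genes, -0.90 for neutrophil markers and 0.25 for macrophage markers, or -1.13, -0.46 and 0.30 without the cell of each library that held most of their UMIs. Hypoxia genes had a median of -0.24 in the CD8 T-like class, or -0.062 with thinned cells, and T cell activation genes -0.045. The vesicle-docking gene Sytl3 had a ratio of 1.66 (1.44 to 1.92) and the anti-apoptotic gene Bcl2a1a 1.72 (1.51 to 1.96), while the carbonic anhydrase gene Car2 had 0.564 (0.475 to 0.669). Gzmc had a ratio of 1.56, which was 0.883 without the top cell of each library.

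Regulatory T-like cells (cluster 14, 92 vehicle and 88 GB1275 cells) had higher naive and memory genes and lower cytotoxicity genes in the GB1275 library. The first list had 6 of 8 members higher, with a median of 0.62 (0.207 to 0.839); Ccr7, the lymph node homing receptor gene, had a ratio of 2.27 (1.63 to 3.19). NF-kB genes were higher for 19 of 26 members, with a median of 0.28, and the NF-kB subunit gene Rel had a ratio of 2.25 (1.86 to 2.74). Cytotoxicity genes were lower for 7 of 10 members, with a median of -0.32, and the perforin gene Prf1 had a ratio of 0.373 (0.226 to 0.599). Markers of other cells had medians there of -0.16 for CD8 T cell markers, -0.28 for macrophage markers and -0.19 for neutrophil markers, or -0.20, -0.26 and -1.25 without the cell of each library that held most of their UMIs. In cluster 10, which mixed CD4 T cell and type 2 innate lymphoid cell genes, all 10 measured cytotoxicity genes and all 10 exhaustion genes were lower, with medians of -0.40 and -0.37. Markers of other cells had medians in cluster 10 of -1.36 for neutrophils, -0.48 for macrophages and 0.003 for CD8 T cells. Without the cell of each library that held most of their UMIs these medians were -0.67, -0.49 and 0.001.

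Neutrophil-like cluster 2 was compared by itself, because the sum of the 3 neutrophil-like clusters shifted the median of all genes by 0.12. Interferon gamma response genes were lower for 16 of 17 members, with a median of -0.61; Gbp2 and Gbp5 had ratios of 0.590 (0.550 to 0.633) and 0.623 (0.556 to 0.696), and the cytokine-signalling inhibitor gene Socs1 had 0.603 (0.478 to 0.758). All 4 T cell chemokine genes were lower, with a median of -0.57. Type I interferon genes had a median of -0.011, with Rsad2, an antiviral enzyme, at 1.57 (1.29 to 1.91) and Isg15 at 0.739 (0.677 to 0.807). Neutrophil granule genes had 3 of 8 members higher and 5 lower, with a median of -0.42 (-0.626 to 0.054), and glycolysis genes had a median of -0.19. Among markers of other cells, macrophage markers had a median of -0.40 and the 4 measured erythroid genes -8.33; without the cell of each library that held most of these UMIs the medians were -0.34 and -1.56. Fkbp5 had a ratio of 6.57 (3.99 to 11.4), the BCL2-family gene Bcl2l15 6.64 (4.03 to 11.5), and the linker histone gene H1f0 0.335 (0.229 to 0.479).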

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

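The differences between clusters and the shares of unnamed clusters below were picked out after the results were seen, and no test of them was possible.

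Type I interferon response genes had a median log2 ratio of 0.13 in macrophage cluster 1 and -0.15 in cluster 6, a difference of 0.28 between clusters of the same libraries, which was not tested. T cell chemokine genes had a median of 0.34 in cluster 3 and -0.31 in macrophage cluster 13, a difference of 0.65 that was not tested. Clusters 3 and 6 are given by number, since only their marker scores place them among the macrophage clusters. MHC class II genes had a median of 0.22 in cycling macrophage cluster 18 and -0.40 in macrophage cluster 13, a difference of 0.63 that was not tested.

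Cluster 5, led by hemoglobin and acinar genes, enters the counts of genes across clusters and the values over all clusters. It held 4.82% of vehicle cells (4.26% to 5.44%) and 8.55% of GB1275 cells (7.77% to 9.38%), with median UMIs of 1628 and 1316. Few of its cells carried the acinar genes: Ctrb1 was found in 3 vehicle and 0 GB1275 cells of the cluster. In the GB1275 library 100% of the acinar UMIs lay outside cluster 5, whose second class was macrophage. Cluster 7, which was left unnamed because neutrophil and eosinophil markers scored alike, held 4.71% of vehicle cells (4.15% to 5.32%) and 6.47% of GB1275 cells (5.79% to 7.21%), with median UMIs of 681.5 and 687.5. Acinar enzyme genes were at 210.6 CPM over all vehicle cells and 30.2 CPM over all GB1275 cells, and 5 cells held 97.4% and 96.2% of these UMIs.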

How the results depend on the processing

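Some of the settings counted here were chosen only after the data were seen. These were a floor of 2000 UMIs, leaving out the top cell of each library, and counting cluster 7 as neutrophil. Another was leaving the unnamed mitochondrial cluster out of the macrophages when no barcode filter was used. Of 97 alternative values of the 12 share ratios, 92 stayed within the counting interval of the reported value, 4 moved beyond it and 1 reversed. Of 216 values of the 17 list medians named in the design, 169 stayed within it, 42 moved and 5 reversed. Of 183 values of 14 other list medians, 125 stayed, 55 moved and 3 reversed, and of 364 values of 34 named genes, 285 stayed, 78 moved and 1 reversed. Across settings the share ratio of neutrophil-marker clusters ranged from 0.689 to 0.779, or was 0.860 with cluster 7 counted, of CD8 T-like cells from 1.08 to 1.24, of cluster 20 from 0.068 to 0.113 and of conventional dendritic-like cells from 1.24 to 1.48. The monocyte medians of interferon gamma genes (-0.468 to -0.247) and type I interferon genes (-0.17 to -0.056) kept their sign.

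In what follows the cause was not tested. With no barcode filter the macrophage share ratio was 1.006, and macrophage medians were -0.009 for T cell chemokines and -0.124 for the mitochondrial genome, where an unnamed low-UMI cluster led by mitochondrial genes counted as macrophage. Without that cluster the share ratio was 0.939, and the medians were 0.027 for T cell chemokines, 0.095 for the mitochondrial genome, 0.101 for NF-kB and 0.044 for MHC class II. The monocyte MHC class II median was 0.165 with no barcode filter. With the stricter filter macrophage medians were 0.033 for MHC class II, 0.158 for NF-kB, 0.254 for T cell chemokines and 0.027 for interferon gamma, and monocyte medians 0.163, 0.227 and -0.245 for the first 3. With doublets kept monocyte medians were 0.091 for MHC class II and -0.352 for T cell chemokines, and the macrophage T cell chemokine median 0.116. At Leiden resolution 0.5, which gave no monocyte cluster, macrophage medians were 0.021 for MHC class II, -0.044 for T cell chemokines and 0.026 for type I interferon. At resolution 2.0 share ratios were 1.706 for cycling CD8 T-like and 0.596 for named neutrophil-like cells, macrophage medians 0.098 for NF-kB and 0.015 for interferon gamma, and monocyte medians 0.153 for MHC class II and -0.235 for T cell chemokines. With listed genes in the clustering macrophage medians were 0.047 for MHC class II, 0.137 for T cell chemokines and 0.010 for interferon gamma, and the monocyte MHC class II median 0.139. As unweighted sums macrophage medians were 0.038 for MHC class II, 0.105 for NF-kB and 0.016 for T cell chemokines. Weighted to the same mix, CD8 T-like medians were -0.096 for cell cycle, 0.004 for cytotoxicity and -0.020 for exhaustion. As a mean over cells macrophage medians were 0.045 for MHC class II and 0.016 for interferon gamma, the monocyte MHC class II median 0.119, and CD8 T-like medians -0.042 for cytotoxicity and 0.027 for naive and memory genes. With cells thinned to 1000 UMIs macrophage medians were 0.039 for MHC class II, 0.136 for NF-kB, -0.194 for STING, 0.117 for T cell chemokines and -0.147 for interferon gamma; monocyte medians were 0.095 for MHC class II, 0.345 for NF-kB, -0.468 for interferon gamma and 0.033 for hypoxia; the CD8 T-like cytotoxicity median was -0.049. With members of at least 50 CPM macrophage medians were -0.091 for interferon gamma and -0.078 for type I interferon. Without cells under 2000 UMIs the macrophage share ratio was 0.993. Without the top cell of each library the ratio of Gzmc in CD8 T-like cells was 0.883.

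Thinning left out 397 vehicle and 542 GB1275 cells, and the floor of 2000 UMIs 822 and 1018. Depth limits clusters under 50 cells in a library, which were not compared in expression, and cells under 500 UMIs, which were not analysed here. No paired analysis was possible because each group had 1 library of pooled mice.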

Other observations

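Of the tests below, those of scaling and depth, free RNA, blood, low-UMI barcodes and doublets, and the count with clusters 7 and 8, were chosen only after the result was seen; those of glucocorticoid targets, time of day and the UMI floor were fixed before their values were looked at.

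Conventional dendritic cell-like cells (cluster 11, 97 vehicle and 121 GB1275 cells) had lower cell cycle genes and higher maturation and costimulation genes in the GB1275 library. Of 29 cell cycle genes, 22 were lower, with a median of -0.75 (-0.865 to -0.526); Ccnb2, Ube2c and Birc5, all active in mitosis, had ratios of 0.376, 0.404 and 0.422. Dendritic cell maturation genes were higher for 8 of 10 members, with a median of 0.23, and costimulation genes for 4 of 5, with a median of 0.48; the CD28 ligand gene Cd86 had a ratio of 1.40 (1.24 to 1.59). The lectin genes Cd209a and Clec10a, markers of type 2 conventional dendritic cells, had ratios of 3.42 (2.81 to 4.19) and 1.79 (1.66 to 1.93), and macrophage markers had a median of 0.67 and neutrophil markers -0.89 in the same cluster, or -0.17 and -0.39 without the cell of each library that held most of their UMIs.

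Plasmacytoid dendritic cell-like cells (cluster 17) had lower dissociation and heat shock genes, with a median of -0.39, and all 9 MHC class II genes lower, with a median of -0.24, beside medians of -0.91 for neutrophil markers and -0.20 for macrophage markers. Jun had a ratio of 0.422 (0.360 to 0.492) there, and the transcription factor gene Klf4 had 3.75 (2.48 to 5.82). In cluster 8, unnamed but with neutrophil markers, type I interferon genes were higher for 19 of 30 members, with a median of 0.52, among them Rsad2 at 2.103 (1.63 to 2.73) and Rtp4 at 2.30 (1.53 to 3.51). All 14 glycolysis genes were lower in that cluster, with a median of -0.33; the hexokinase gene Hk2 had a ratio of 0.587 (0.510 to 0.674). In B-like cells (cluster 19) the transcriptional regulator genes Id2 and Myc had ratios of 0.233 (0.140 to 0.373) and 0.341 (0.182 to 0.610). The ratio of Myc was 0.203 without the top cell of each library. Markers of other cells had medians there of -4.45 for CD8 T cells, -0.87 for macrophages and -0.90 for neutrophils. Without the cell of each library that held most of their UMIs these medians were -2.75, -0.85 and -1.81.

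Fkbp5, Tsc22d3, Klf9 and Mt2, all known targets of the glucocorticoid receptor, were higher in the GB1275 library in most clusters. Scaling is argued against by the values in macrophages, where the median log2 ratio of all genes was -0.006. The median log2 ratio of these 4 genes there was 1.14 with the median of all genes set to 0 and 1.22 with thinned cells. Thinning keeps each gene's expected share of a cell's UMIs, so the last value says little about depth. Free RNA of 1 source is argued against for Fkbp5, the only gene of these 4 that was checked. Its excess of UMIs per cell ranged from -0.079 to 1.74 over clusters, the highest being 4.52 times the median. The lowest came from cluster 12, where its CPM was higher in GB1275 (ratio 1.40). Median UMIs per cell in cluster 12 were 22819 in vehicle and 13126 in GB1275, so this excess also depends on depth. Glucocorticoid exposure of the GB1275 pool, through stress or handling for example, is a candidate explanation: of 13 further targets, 11 were measured and 9 were higher over all clusters, with a median of 0.20 (0.164 to 0.234, 100th percentile), and the list lay above the 95% range of random lists in 10 of 19 clusters, 7 of 7 macrophage and monocyte clusters but 0 of 5 lymphocyte clusters. Against it, the list lay below that range in lymphocyte cluster 10, with 8 of 9 members lower and a median of -0.27, although the 4 genes first noticed had a median of 1.21 there. A different time of day at collection stays open, with a median of 0.36 (0.085 to 0.523) for 6 clock output genes, between the bounds of 0.2 and 0.5. This value was taken without the floor of 10 CPM, since these genes lay between 1.59 and 9.98 CPM over all cells, where Nr1d2 was at 0.46 and Ciart at -0.18. GB1275 itself cannot be told apart from either, because each group has 1 library.

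Neutrophil-like clusters held a lower share of the GB1275 library. Loss below the floor of 500 UMIs stays open. In the named clusters 5.23% of vehicle and 5.76% of GB1275 cells held under 1000 UMIs. Both were under the limit fixed in advance, which argues against such loss for these clusters. But 21.1% and 31.6% did once unnamed clusters 7 and 8 were counted, a choice made after the result was seen. Cluster 7 had a share ratio of 1.37. Blood cells in the vehicle tumours may have contributed: hemoglobin genes were at 1749 CPM in the vehicle library and 582.0 CPM in the GB1275 library, 3.01 times as high. In each library 5 cells held 58.0% and 98.2% of these UMIs, and without them 734.4 CPM and 10.4 CPM remained; 29.9% of vehicle and 11.4% of GB1275 cells held such UMIs. The share ratio of B cells, which blood also brings, decides nothing, at 1.17 (0.795 to 1.71). Cluster 5, with erythroid as its highest class, had a share ratio of 1.77 (1.51 to 2.08). Its share cannot decide on blood, since its next class was macrophage and few cells held most hemoglobin UMIs. Cells with at least 100 hemoglobin UMIs numbered 11 in the vehicle library and 2 in the GB1275 library. An effect of GB1275 cannot be told apart from a difference between pools, because each group has 1 library.

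Cycling CD8 T-like cluster 12 held a higher share of the GB1275 library. It held 49 GB1275 and 7 vehicle cells under 2000 UMIs, but low-UMI barcodes are argued against as the whole cause, because without cells under 2000 UMIs the share ratio was 1.92 (1.34 to 2.77), from 84 and 52 cells. Doublets stay open: the ratio was 2.41 (1.79 to 3.26) with the highest scores kept and 2.49 (1.82 to 3.45) without them, a difference within the counting interval, and doublets that the scores missed were not tested. An effect of GB1275 cannot be told apart from a difference between pools, because each group has 1 library.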
